A study of Clonorchis sinensis with 4 samples.

How the data were processed

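Small RNA was sequenced from the Chinese liver fluke Clonorchis sinensis as 4 libraries, 1 each of eggs, metacercariae (the encysted larvae carried by freshwater fish), adult worms and extracellular vesicles secreted by adult worms. Per the labels' protocols, total RNA was extracted with Trizol and libraries followed the standard Illumina procedure. With 1 library per group there is no replicate check, no test between conditions was run, and the labels carry no replicate numbers.

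The authors deposited raw tag counts per small RNA entry, per the file headers, with the library total in the header of the count column. The deposited counts of every library summed to that total. Each entry carries a class, which is a known miRNA (names from Schistosoma mansoni, Schistosoma japonicum and C. sinensis), a predicted miRNA (numbered novel_mir in the files), a piRNA (numbered novel_pir), an Rfam family, or a pooled class of repeat, exon, intron or intergenic tags. The authors' normalized column is headed TPM and equals the deposited count divided by the header total, times 1000000, which is RPM of annotated tags with no length correction. The aligner, the class annotation tools, the piRNA caller and the genome builds are not given in the sources used here. For the vesicle library the authors also gave the mapped tags as a percent of clean tags, tag counts per reference scaffold and a table of insert lengths, per the file headers. A deposited table gives the fraction of each base by read position, and it is not used here. The scaffold table names scaffolds of C. sinensis, Opisthorchis viverrini, Fasciola hepatica and S. mansoni. Coordinates are therefore given with the scaffold name as deposited, and many predicted miRNAs lie on scaffolds of a related fluke. In adults 31 of 99 lay on O. viverrini and 11 on F. hepatica scaffolds. The same numbers were 30 and 11 of 92 in eggs and 27 and 12 of 108 in metacercariae. The deposited miRNA and piRNA tables of a stage held the same entries, counts and classes, so miRNA results use the miRNA entries and piRNA results the piRNA entries. 1 deposited column of counts belonged to another species' vesicles and was not used.

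Annotated tags numbered 20541335 in eggs, 20490790 in metacercariae, 19404746 in adults and 2361216 in vesicles. The miRNA totals were 4339591, 8559610, 3567193 and 302004 tags in the same order. A count of 0 allows 3 tags, which is 0.691, 0.350, 0.841 and 9.93 RPM of miRNA tags. Known miRNAs are listed from 1 tag upward, so an unlisted one has 0. Predicted miRNAs and piRNAs are listed from 10 tags upward, so an unlisted one has at most 9, and 9 was used in its place. Folds that rest on such a value are lower bounds and are written "at least". Intervals are exact at 95% and, like the floors, cover only the counting error of tags taken as independent, with 1 library per group. Tags without molecular identifiers are not independent molecules, so the intervals can be too narrow even for counting error.

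Counts were scaled to RPM of the library's miRNA total, or of its piRNA total. An entry was counted as higher or lower when its fold was at least 4 on values with a pseudocount of 1 RPM, the higher library held at least 10 tags, and the exact conditional binomial interval of the ratio lay beyond 2-fold. Printed folds are ratios without the pseudocount, except those under another scaling, which include it. Vesicles were set against adults over 51 entries named in both tables, scaled to the sum of those entries. These were 36 known miRNAs and 15 predicted miRNAs matched by overlapping coordinates, since the vesicle table numbers its predicted miRNAs anew. The vesicle table's other 12 predicted miRNAs had no overlap, and its piRNAs were not compared. A stage-specific miRNA had at least 10 tags in 1 stage and was at 0 or unlisted in the other stages. Shares carry Clopper-Pearson intervals. The median log2 fold of a list was ranked among 10000 random lists of the same size, each member drawn from the 20 entries nearest in mean expression. Draws took known and predicted miRNAs alike. List members are known miRNAs that often share a family and are not independent, so the percentiles are descriptive.

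Named entries followed a rule fixed before the data were examined. They were the 10 largest folds each way among entries counted by the size rule with a mean of at least 10 RPM, the 5 most abundant of each library, and the members of fixed lists. The lists were heterochronic (let-7, miR-125, miR-100, lin-4), muscle (miR-1, miR-133, miR-206), nervous system (miR-124, miR-7, miR-9, miR-153, miR-219, miR-96, miR-183), the miR-71/miR-2 cluster (with miR-13 and miR-36), trematode vesicle cargo, miRNAs abundant in female schistosomes, other flatworm families, and vertebrate families of host cells. For piRNAs the rule took the 3 largest folds each way and the 3 most abundant per library. A list of plant miRNA families and the entries said to be chosen after their values were seen lie outside it. The similarity of libraries was first computed with unlisted predicted miRNAs at 0 and then with 9, after the values were seen, to match the comparisons.

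Alternatives covered median-of-ratios size factors, edgeR's TMM factors (scaling only), totals without the most abundant entry, the authors' RPM, other pseudocounts, minimums and folds, and summing entries of the same name or LTR (long terminal repeat) locus. The pseudocount stayed at 1 RPM of each scaling. With the authors' RPM, which counts all annotated tags, it therefore weighs more against miRNA and piRNA entries. The planned 5' base and length profile of piRNAs was not made, because no piRNA sequence was used here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, with R 4.3.3 and edgeR 4.0.16 for TMM. The size rule was tested on simulated Poisson counts. For eggs against adults over 167 miRNA entries it recovered 65% of 8-fold and 90% of 32-fold changes, for metacercariae against adults over 182 entries 90% and 95%, for eggs against metacercariae over 186 entries 90% and 80%, and for vesicles over 51 entries 100% and 100%. For piRNAs it recovered 51% and 74% in eggs against adults over 5171 entries, 54% and 76% in metacercariae against adults over 5501, and 48% and 77% in eggs against metacercariae over 4800. No unchanged entry was called in any of the 7 simulated comparisons. These simulations drew counting error only and scaled by the totals set before the changes. They therefore do not test errors from scaling, composition or differences between replicates. Of 300 simulated lists of 6 unchanged members, 9.33% lay outside percentiles 5 to 95 when the values of all entries were redrawn for each list. A first form of this check kept 1 set of simulated values and put a larger share outside, so percentiles near 5 and 95 are approximate.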

Results

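The series asked which miRNAs and piRNAs mark the eggs, metacercariae and adults of C. sinensis, and a further library covered vesicles shed by adults. Each group was 1 library, so every difference below compares libraries and has no replicate check. The tables listed 55 known and 138 predicted miRNAs over the 3 stages, of which 52 and 66 were listed in every stage.

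Known and predicted miRNAs together made up 41.8% of annotated tags in metacercariae (95% interval 41.8 to 41.8), 21.1% in eggs (21.1 to 21.1), 18.4% in adults (18.4 to 18.4) and 12.8% in vesicles (12.7 to 12.8). Adults were led by bantam, a miRNA that promotes growth in flies, with 31.5% of miRNA tags, followed by miR-71a-5p (20.4%), miR-2a-3p (10.6%), miR-277 (6.70%) and miR-10-5p (3.94%). Eggs were led by miR-71a-5p (25.6%), then the predicted miRNA novel_mir1 (14.5%), bantam (11.1%), the predicted novel_mir73 (9.32%) and miR-36b-3p (8.73%). In metacercariae miR-71a-5p (25.7%) was followed by miR-124a-3p (17.3%), miR-1 (13.5%), miR-2a-3p (12.7%) and bantam (6.30%). In vesicles miR-71a-5p alone held 69.3% (69.1 to 69.4), ahead of bantam (5.80%), miR-61-3p (4.80%), miR-10-5p (3.59%) and the predicted miRNA on scaffold LN627598 that the stage tables call novel_mir73 (3.44%). The 5 most abundant entries took 73.1% of miRNA tags in adults, 69.2% in eggs, 75.5% in metacercariae and 86.9% in vesicles. By family, miR-71 was first in eggs (29.2%), metacercariae (25.9%) and vesicles (69.6%), and bantam was first in adults (31.5%).

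**Figure D1:**
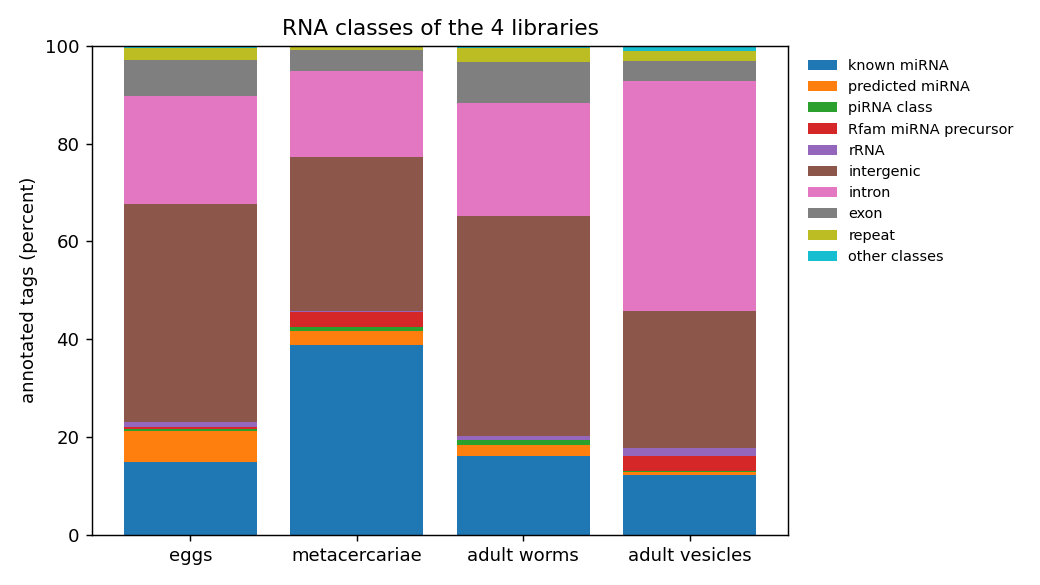
RNA classes as deposited, in percent of annotated tags (vertical axis), as stacked bars for the 4 libraries, 1 library each. Known miRNAs reach 38.8% in metacercariae against 16.1% in adults, and intron tags reach 47.1% in vesicles.

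Eggs differed from adults first in the miR-36 family, a family of early embryos in nematodes. miR-36b was 15.4-fold higher in eggs (14.6 to 16.3), miR-36b-3p 14.0-fold (13.8 to 14.2) and miR-36a-3p 11.6-fold (10.4 to 13.0). The predicted miRNAs novel_mir1 (scaffold NW_008751893, 603415 to 603479), novel_mir73 (scaffold LN627598, 1961 to 2031) and novel_mir76 (scaffold NW_008751684, 2387518 to 2387580) were 13.8-fold, 10.7-fold and 8.77-fold higher. Lower in eggs were miR-10-5p, a miRNA of the Hox clusters in many animals, by 15.0-fold (14.7 to 15.3), miR-755-3p by 12.0-fold (11.3 to 12.8) and let-7-3p by 13.6-fold (9.07 to 21.1). Among entries counted as lower with a mean of at least 10 RPM, the largest folds were in predicted miRNAs, with novel_mir15 (scaffold DF143035) at 44.9-fold, novel_mir148 at 25.8-fold, novel_mir3 at 23.8-fold and novel_mir12 at 17.3-fold. novel_mir12 (1040091 to 1040173) and novel_mir148 (1040276 to 1040359) are neighbours on scaffold NW_008751832. novel_mir74 and novel_mir8 were 14.8-fold and 10.5-fold lower, and novel_mir52 was lower too, with 148 tags in adults and none listed in eggs. novel_mir80, miR-2d-3p, miR-71b-5p and miR-2c-3p were 5.70-fold, 5.11-fold, 4.88-fold and 4.28-fold higher in eggs.

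In all, 11 of 167 miRNAs were higher and 35 lower in eggs than in adults. Of the 13 members of the miR-71/miR-2 cluster list, which here includes miR-36, 6 were higher and 0 lower, of which miR-2c-3p did not pass without the most abundant entry (3.94-fold). The 6 include the miR-36 entries above. The most abundant miR-2 entry, miR-2a-3p, had a ratio of 0.557 (0.555 to 0.560). The miR-2 family as a whole had a ratio of 0.739, and its direction turned with median-of-ratios size factors. The list's median log2 fold was 1.63, at percentile 99.4 of matched random lists. In the heterochronic list, whose let-7 times larval transitions in nematodes, 2 of 3 members were lower, let-7-3p and miR-125c-5p (1 tag in eggs against 37, and not counted with the authors' RPM), and let-7-5p had a ratio of 0.255. With the authors' RPM miR-125c-5p held 0.0487 in eggs and 1.91 in adults, so the pseudocount of 1 RPM removed its call. The list median was -3.21, at percentile 1.05. With 3 members this median is the value of miR-125c-5p alone and rests on its 1 egg tag. In the nervous system list 2 of 8 members were lower, miR-219-5p by 4.22-fold and its second entry miR-219-5p_1 by 5.09-fold, while the median was 0.32 at percentile 95.2. miR-219-5p passed the size rule under 1 of the 4 other scalings (log2 -1.26 with median-of-ratios size factors, -1.78 with TMM, -1.87 with the authors' RPM), and miR-219-5p_1 under 3 (-1.53 with median-of-ratios size factors). No member of the 5 in the muscle list was counted either way (median 0.12, percentile 67.8). Of 7 members of other flatworm families 3 were lower, miR-755-3p, miR-8-3p (9.33-fold) and miR-745-3p (4.92-fold), with a median of -1.46 at percentile 27.0, although miR-745-3p did not pass with median-of-ratios size factors (2.79-fold) or TMM (3.99-fold). The trematode vesicle cargo list had 6 of 24 members higher and 4 lower (median -0.09, percentile 73.9), of which 1 higher and 2 lower calls were lost under a scaling. The female schistosome list had 1 and 1 of 6 (-0.57, percentile 26.5), and its lower member, miR-31-5p_1, was not counted with median-of-ratios size factors (log2 -1.47) or TMM (-1.98). Scaling changed the split, to 22 higher and 19 lower with median-of-ratios size factors and to 11 and 21 with the authors' RPM, which shifted the median log2 fold by 0.80 and 0.20. The authors' RPM also gives the pseudocount more weight, so its split does not reflect scaling alone. TMM shifted the median by 0.29 and left 28 lower. Entries of like name, such as miR-1 with miR-1_1 or bantam with bantam-3p, may share tags, and their sequences were not compared here.

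Metacercariae stood apart from adults in miRNAs of nerve and muscle. miR-124, a neuronal miRNA across animals, was 32.2-fold higher as miR-124a-3p (31.7 to 32.6) and 45.4-fold higher as miR-124b-5p (42.2 to 48.8). The muscle miRNAs miR-133 and miR-1 were 22.8-fold (15.6 to 34.8) and 6.71-fold (6.66 to 6.76) higher. new_miR-001, named from C. sinensis, was 28.5-fold higher (19.6 to 43.0) and miR-307 was 6.06-fold higher. Lower in metacercariae were bantam by 5.00-fold (4.98 to 5.01) and the predicted miRNAs novel_mir1 by 1960-fold (1469 to 2677) and novel_mir124 (scaffold NW_017386003, 3196 to 3237) by 1574-fold (1263 to 1988). The bantam call rested on scaling, at 2.53-fold with median-of-ratios size factors, 2.64-fold with TMM and 2.20-fold with the authors' RPM.

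In the nervous system list 5 of 8 members were higher and 0 lower, which besides miR-124 were miR-7-5p (4.23-fold, but 3.90-fold and not counted without the most abundant entry), miR-7-5p_1 (14.5-fold) and miR-7-3p (5.69-fold). miR-96-5p had a ratio of 1.53, and miR-219-5p and miR-219-5p_1 had ratios of 1.22 and 0.842. The list median was 2.29, at percentile 99.985 of matched random lists. The 8 members belong to miR-124, miR-7, miR-219 and miR-96 only and are not independent. Random lists also drew predicted miRNAs, whose median log2 fold was -0.79 against -0.32 for known ones, so the percentile is descriptive. In the muscle list 3 of 5 members were higher, the last being miR-1a-5p at 4.54-fold, with a median of 2.18 at percentile 99.3. In the miR-71/miR-2 list 1 of 13 members was lower, miR-2c-3p by 6.53-fold (3.30-fold, 3.44-fold and 2.85-fold with those scalings), and the median was -1.09 at percentile 19.0. In the cargo list 1 of 24 members was higher and 4 lower, of which bantam, let-7-3p and miR-2c-3p lost the call under the same 3 scalings, with a median of -1.20 at percentile 3.35. The heterochronic list had 1 of 3 lower (median -1.93, percentile 21.1), let-7-3p, which was not counted with median-of-ratios size factors (log2 -1.28), TMM (-1.34) or the authors' RPM (-1.02). The female schistosome list had 2 of 6 lower (-0.72, percentile 38.6), bantam among them, and other flatworm families 1 of 7 higher (-0.73, percentile 53.1).

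Over 182 miRNAs, 17 were higher and 43 lower in metacercariae than in adults. Of the remaining named entries, novel_mir15, novel_mir76, novel_mir68, novel_mir17 and novel_mir179 were unlisted in metacercariae and at least 2028-fold, 725-fold, 284-fold, 127-fold and 124-fold lower. novel_mir131, novel_mir143 and novel_mir52 were 162-fold, 86.0-fold and 32.3-fold lower. novel_mir36, novel_mir43 and novel_mir136 were at least 21.1-fold, 14.1-fold and 12.3-fold higher, and novel_mir146 was 7.50-fold higher. The split depended on scaling and, with the authors' RPM, also on the heavier pseudocount. It became 30 higher and 12 lower with the authors' RPM, 27 and 23 with median-of-ratios size factors and 25 and 23 with TMM, at shifts of 1.18, 0.92 and 0.87 in the median log2 fold.

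**Figure D2:**
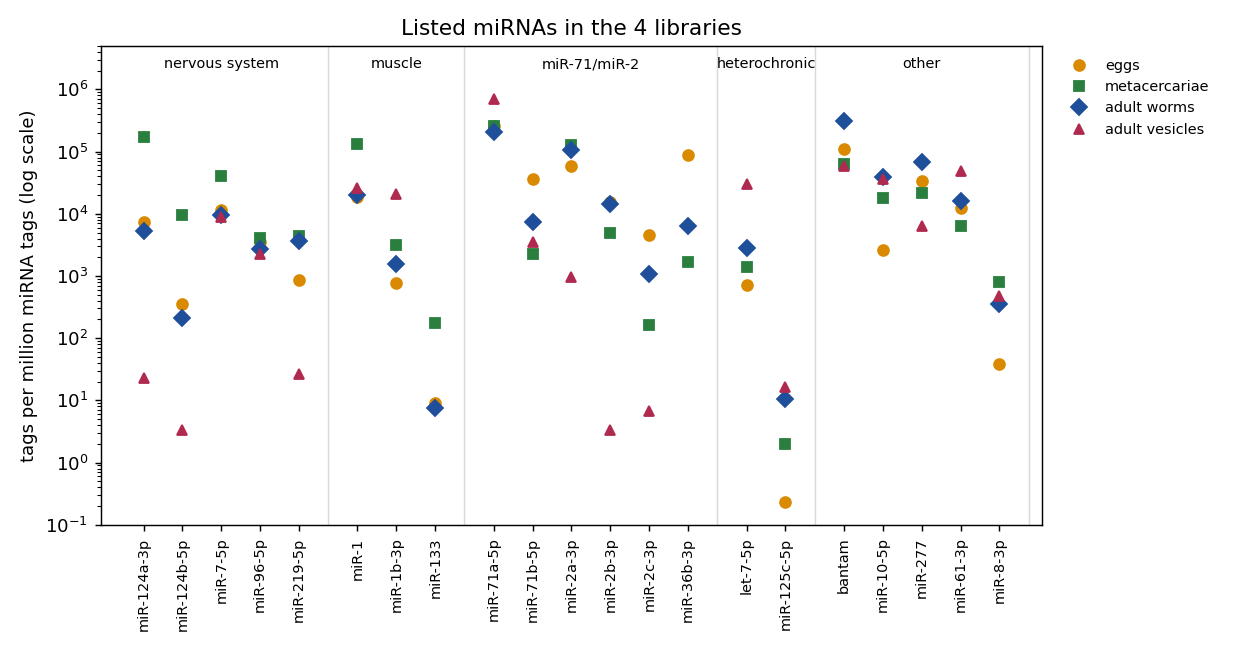
RPM of miRNA tags on a log scale (vertical axis) for 21 listed miRNAs (horizontal axis), 1 point per library, with no point where no tag was listed. miR-124a-3p and miR-1 peak in metacercariae, miR-36b-3p peaks in eggs, and miR-2b-3p and miR-2c-3p are lowest in vesicles.

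Eggs against metacercariae differed in miR-36, miR-71b-5p, miR-2c-3p and miR-2d-3p on the egg side and in miR-124 and miR-133 on the other. miR-36b-3p was 53.0-fold higher in eggs (52.1 to 53.9), miR-36a-3p 41.4-fold (36.2 to 47.5) and miR-2c-3p 27.9-fold (26.5 to 29.5). miR-71b-5p and miR-2d-3p were 16.2-fold and 17.6-fold higher. The most abundant miR-2 entry, miR-2a-3p, had a ratio of 0.466 (0.464 to 0.468), and the miR-2 family as a whole a ratio of 0.700. miR-124a-3p was 23.2-fold lower in eggs (22.9 to 23.4), miR-124b-5p 26.6-fold, miR-133 18.8-fold and miR-8-3p 20.9-fold (17.9 to 24.5). novel_mir1 held 629565 tags in eggs and 46 in metacercariae, a ratio of 26995 (20238 to 36873).

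Over 186 miRNAs, 30 were higher and 30 lower in eggs. In the miR-71/miR-2 list 7 of 13 members were higher and 0 lower, of which miR-2f-3p did not pass with the authors' RPM (3.34-fold), with a median log2 fold of 2.73 at percentile 99.7. In the nervous system list 6 of 8 were lower, with a median of -2.64 at percentile 0.965, and in the muscle list 4 of 5 were lower, with a median of -2.07 at percentile 11.7. The cargo list had 8 members higher and 3 lower of 24 (median 0.73, percentile 96.8), and the female schistosome list 2 higher and 1 lower of 6 (0.80, percentile 88.5). bantam-3p, higher in both lists, did not pass with the authors' RPM (2.60-fold), nor did miR-2f-3p of the cargo list. The heterochronic list had 0 of 3 counted (-1.28, percentile 12.6) and the other flatworm list 1 of 7 lower (-1.57, percentile 16.2). Other named entries higher in eggs were novel_mir124 (413-fold), novel_mir131 (37.3-fold) and, unlisted in metacercariae, novel_mir76, novel_mir68, novel_mir17 and novel_mir179 (at least 6354-fold, 494-fold, 94.7-fold and 51.3-fold). Lower were new_miR-001 (38.8-fold), novel_mir8 (27.8-fold), novel_mir74 (26.3-fold), novel_mir3 (15.4-fold), miR-7-3p (13.2-fold) and novel_mir23 (at least 50.6-fold). The authors' RPM gave 19 higher and 39 lower, at a shift of -0.91 in the median.

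Stage-specific miRNAs were scarce and of low abundance. By the fixed rule 43 were found, 26 in metacercariae, 10 in eggs and 7 in adults, and none was a known miRNA. The rule was stricter for known miRNAs, which 1 tag in another stage excluded, while a predicted one could hold 9. miR-190-5p, with 124, 4 and 1 tags in metacercariae, adults and eggs, was left out this way. So was miR-71b-3p, with 11 tags in eggs, 9 in metacercariae and 2 in adults. The absence of known miRNAs therefore follows in part from the rule. The tag counts of the 43 ran from 10 to 84 with a median of 19. The largest of each stage were novel_mir57 in adults (84 tags, scaffold DF143031, 485466 to 485541), novel_mir172 in metacercariae (68 tags, scaffold DF143656, 41367 to 41440) and novel_mir60 in eggs (56 tags, scaffold DF143747, 39763 to 39818), which were chosen after their values were seen. Since an unlisted predicted miRNA may hold 9 tags, 6 of the 43 had a ratio to each other stage with a counting interval above 2-fold. These were 4 of 7 in adults, 2 of 10 in eggs and 0 of 26 in metacercariae. The metacercaria library held the most miRNA tags, so 10 tags there were 1.17 RPM, below the 2.52 RPM of 9 tags in adults. Its larger number of entries can therefore reflect depth and the listing minimum. Among abundant entries novel_mir1 was listed in every stage, with 629565, 37572 and 46 tags in eggs, adults and metacercariae.

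Across miRNAs, which are not independent replicates, the adult and egg libraries were closest, with Pearson's r of 0.918 and Spearman's rho of 0.905 on log2 values over 167 entries. Adults and metacercariae gave 0.845 and 0.761 over 182 entries, and eggs and metacercariae 0.818 and 0.741 over 186. Vesicles gave 0.588 and 0.531 with adults over 51 shared entries, 0.544 and 0.447 with eggs over 51, and 0.521 and 0.459 with metacercariae over 50.

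Vesicles held tags of 36 known miRNAs and adults of 53, at 302004 and 3567193 miRNA tags. let-7-5p (GGAGGTAGTTCGTTGTGTGGT) was 9.58-fold higher in vesicles (9.31 to 9.86), miR-1b-3p 12.0-fold (11.6 to 12.4) and miR-2162-3p 25.2-fold (17.95 to 35.84). Other miR-1 entries differed from miR-1b-3p, with ratios of 1.18 for miR-1, 0.309 for miR-1_1 and 0.0639 for miR-1a-5p. The miR-1 family as a whole had a ratio of 1.83. miR-2 entries were scarce in vesicles, with miR-2a-3p 119-fold lower (107 to 134), miR-2e-3p 519-fold (239 to 1415), and miR-2b-3p at 1 tag against 50405 in adults, a ratio of 2.14e-04 (5.41e-06 to 0.00119). The neuronal miR-124a-3p was 255-fold lower (124 to 634), miR-219-5p 150-fold (75.9 to 346) and miR-281 917-fold (254 to 7577). These rest on 7, 8 and 2 vesicle tags, and the other entry miR-281-3p had a ratio of 0.867 (0.438 to 1.56). bantam, second in vesicles, was 5.94-fold lower (5.86 to 6.03), but 2.07-fold with median-of-ratios size factors, 3.99-fold with TMM and 2.73-fold without the most abundant entry, so its call rested on scaling. In the same library host-cell families held 4479 RPM of annotated tags against 36.2 in adults, and the Rfam let-7 class 16202 tags against 1.

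Of 51 shared entries, 6 were higher and 22 lower in vesicles. In the miR-71/miR-2 list 4 of 7 members were lower and 0 higher, at a median log2 fold of -6.90 and percentile 0.430, while miR-71a-5p itself had a ratio of 3.10 (3.09 to 3.12). In the cargo list 1 of 18 was higher and 9 lower (median -2.00, percentile 8.92), in the nervous system list 3 of 6 were lower (-3.07, percentile 20.8) and in the female schistosome list 3 of 5 (-2.44, percentile 16.7). Of these lower calls bantam, let-7-3p, miR-277 and miR-31-5p_1 in the cargo list, and bantam and miR-31-5p_1 in the female list, were lost under at least 1 scaling. The heterochronic list split 1 higher and 1 lower of 3 (0.50, percentile 68.2), and the lower one, let-7-3p on 3 vesicle tags, was not counted with median-of-ratios size factors (log2 -1.59) or without the most abundant entry. The muscle list split 1 and 1 of 4 (-0.72, percentile 76.1) and other flatworm families 1 and 3 of 6 (-2.01, percentile 54.9). Named predicted miRNAs, by stage name, were novel_mir40 (20.9-fold higher), novel_mir141 (7.13-fold higher), novel_mir34 (4.91-fold higher, but 3.51-fold and not counted with the authors' RPM), novel_mir70 (86.8-fold lower) and novel_mir10 (58.1-fold lower). Predicted miRNAs enter this comparison only from 10 vesicle tags upward, and 9 vesicle tags are 29.8 RPM of miRNA tags. novel_mir40 and novel_mir141 held 15.3 and 24.0 RPM in adults, so at equal RPM they would be expected to go unlisted in vesicles. Their calls as higher therefore follow in part from the listing minimum. miR-2c-3p and miR-124b-5p were 176-fold and 69.6-fold lower on 2 and 1 vesicle tags, with intervals of 48.7 to 1455 and 12.5 to 2754. Among 17 known adult miRNAs with no vesicle tag, miR-219-5p_1 and miR-36b-3p were at least 1161-fold and 679-fold lower as RPM of known miRNA tags. In contrast miR-36a-3p, with 66 vesicle tags, had a ratio of 2.12 (1.60 to 2.77) over the shared entries. With median-of-ratios size factors the split was 13 higher and 15 lower, with TMM 11 and 17, and without the most abundant entry 12 and 16, at median shifts of 1.51, 0.57 and 1.12. miR-71a-5p dominated vesicles, and leaving it out of both libraries also gave 12 higher entries.

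By class, intron tags made up 47.1% of annotated vesicle tags (47.0 to 47.1), intergenic tags 28.1% (28.0 to 28.1), known miRNAs 12.1% (12.1 to 12.2) and Rfam miRNA precursors 2.96% (2.94 to 2.98). Of the host-cell list, no family was among the known miRNA entries, and 15 were listed as Rfam families. Together they held 4479 RPM of annotated tags in vesicles, against 36.2 in adults, 38.9 in eggs and 76.1 in metacercariae. The liver family mir-122 held 5577 vesicle tags and 43 adult tags, a ratio of 1066 (790 to 1474), the erythroid family mir-486 1082 and 0, at least 2964-fold, and the widely expressed mir-21 1464 and 0, at least 4010-fold. mir-451 was seen in every library, at 335 RPM in vesicles and 27.8 in adults.

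**Figure D3:**
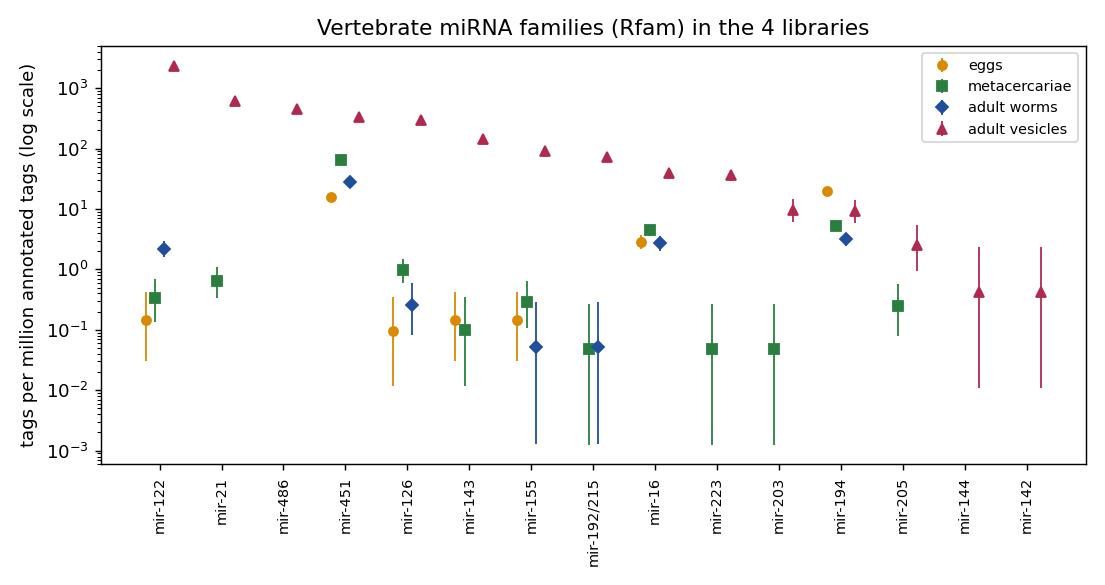
RPM of annotated tags on a log scale (vertical axis) for 15 vertebrate miRNA families (horizontal axis) in the 4 libraries, with exact 95% intervals for counting error and no point at a count of 0. Vesicles hold the most of mir-122, at 2362 RPM, and eggs hold the most of mir-194, at 19.6.

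The piRNA class, entries placed by the authors on LTR/Gypsy retrotransposon loci, held 9167 RPM of annotated tags in adults (9124 to 9209), 6168 in metacercariae (6134 to 6202) and 4803 in eggs (4773 to 4833). Adults listed 4573 entries on 161 loci, metacercariae 3853 on 143 and eggs 3189 on 135, and 2070 entries were listed in every stage. The same locus, scaffold DF143974.1 from 133707 to 136377, was first in adults (12.9% of piRNA tags) and eggs (15.1%), and the locus on scaffold DF142881.1 from 693483 to 694702 was first in metacercariae (19.9%). The 10 most abundant loci held 59.3% of piRNA tags in adults, 60.5% in eggs and 57.9% in metacercariae.

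Relative to the piRNA total, 123 of 5171 entries were higher and 39 lower in eggs than in adults, 167 and 78 of 5501 in metacercariae than in adults, and 118 and 82 of 4800 in eggs than in metacercariae. The largest folds higher in eggs against adults were novel_pir3977 (19.3-fold, 10.9 to 37.1) and novel_pir3982 (14.5-fold), both on the DF143974.1 locus, and novel_pir4972 (12.3-fold) on the DF142881.1 locus. The largest lower were novel_pir1991 and novel_pir2015, at least 9.80-fold and 8.01-fold on scaffold DF143043.1 (510899 to 512225), and novel_pir552 (6.60-fold). Against adults, metacercariae were highest in novel_pir2989 (at least 15.6-fold), novel_pir5256 (14.5-fold) and novel_pir5253 (13.3-fold), and lowest in novel_pir4517 (at least 14.9-fold), novel_pir3072 (13.9-fold) and novel_pir263 (9.61-fold). Eggs against metacercariae were highest in novel_pir4054, novel_pir1667 and novel_pir3991 (at least 27.3-fold, 15.2-fold and 14.4-fold) and lowest in novel_pir5422 (16.7-fold), novel_pir5399 and novel_pir4835 (at least 14.0-fold and 13.3-fold). The most abundant entries were novel_pir887, novel_pir1649 and novel_pir1268 in adults (823, 723 and 684 tags), novel_pir5480, novel_pir4279 and novel_pir1337 in eggs (880, 688 and 514) and novel_pir5480, novel_pir1268 and novel_pir918 in metacercariae (868, 707 and 491). The direction of the split followed the scaling. The authors' RPM gave 2 higher and 28 lower in eggs and 2 and 26 in metacercariae against adults, and 7 and 13 in eggs against metacercariae, with median shifts of -0.63, -0.41 and -0.22. In that scaling the pseudocount also weighs far more, since piRNAs are a small part of annotated tags. Its counts therefore do not reflect scaling alone, and 18 of the 162 calls in eggs against adults were kept. Median-of-ratios size factors gave 55 and 80, 102 and 116, and 85 and 116, and TMM gave 61 and 80, 113 and 112, and 87 and 101.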

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

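All tests in this part were chosen after the result was seen. Several signals lay in classes that the stage and vesicle comparisons do not use, each far above the 3 tags that a count of 0 allows. The vesicle library held 4479 RPM of annotated tags in vertebrate host-cell families, 3822 in Y RNA and 4160 in bacterial small subunit rRNA. The Rfam class of transfer-messenger RNA, a bacterial RNA, held 2742 RPM in eggs and 2333 in adults. Bacterial small subunit rRNA held only 4.82 RPM in eggs and 2.01 in adults, and bacterial large subunit rRNA 11.9 and 15.4. Whether the transfer-messenger tags are bacterial was not tested. Inserts of 13 nt made up 75.4% of the tags in the vesicle length table, and 35.8% of mapped vesicle tags lay on a single C. sinensis scaffold, DF143900.1. Plant miRNA families held 977 RPM in eggs.

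Of 15 host-cell families, 12 were at least 10-fold above adults, and the median ratio to adults was 233 with adult counts under 3 taken as 3. Fluke tags placed in vertebrate families by likeness would be held by whole adults too, if both libraries were annotated alike. The annotation tools are not given, and some Rfam classes of families known in the flukes were raised as well. The mir-71, mir-10 and mir-7 classes were 10.6-fold, 364-fold and 949-fold above adults, while the mir-2 and mir-124 classes held 0 vesicle tags. The median therefore cannot decide this for the host-cell families. Host RNA in the vesicle preparation may account for them. Uptake by worms and release in vesicles stays open, since no vesicle-free fraction was analysed here. Adults held 36.2 RPM of these families, eggs 38.9 and metacercariae 76.1, but 539 of the 703 adult tags were mir-451 and 8 of the 15 families had no adult tag.

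In the gap between miR-71a-5p and miR-2, miR-2a-3p stood at 52.2 tags per 100 miR-71a-5p tags in adults and 0.141 in vesicles, and all 4 miR-2 entries named in both tables were counted as lower. Placement of miR-2 tags in the Rfam mir-2 class is argued against, since that class held 0 vesicle tags where about 136264 were missing at the miR-71a-5p ratio. Intron tags were 24 percentage points more of the vesicle library than of adults, so miR-2 tags left in that class cannot be told apart from absence without the sequences. More miR-71a-5p alone is argued against, since the median of the miR-71/miR-2 list was -5.78 with totals that leave out miR-71a-5p in vesicles and bantam in adults. Packing that leaves out miR-2 could explain the 4 lower entries but is untested with 1 vesicle library.

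The ratio of adults to eggs was weighed last. The 5 plant families with at least 100 egg tags had adult to egg ratios of RPM from 0.0671 to 0.0971, and the 10 named miRNAs higher in eggs, at 0.0564 to 0.203, had a median ratio 1.20 times that of the plant families. These miRNAs were taken for their large egg over adult folds, so the nearness of the medians decides nothing. The 5 plant families were likewise kept for their egg tags, and families below that minimum differed. MIR171 held 34 adult and 4 egg tags, and MIR164 held 1 and 86. The range of the 5 families is therefore not one ratio of all plant families. Tags leaking among all 3 stage libraries are argued against by the median metacercaria to egg ratio of the 5 plant families, 0.00452. A fixed share of egg RNA in the adult library and transcription in adult tissue cannot be told apart. Of the 10 miRNAs, 5 lay above the interval of those 5 plant families together and 3 lay below it.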

How the results depend on the processing

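Alternatives were set before the data were examined, unless said to be added after seeing the data. No paired analysis was possible because each group is 1 library and the labels carry no replicate numbers. The planned piRNA sequence features were not run, since no piRNA sequences were used here. A count was taken as unmoved within 1.5 times, a correlation within 0.05 and a log2 value within 0.1, the last limits being set after the data were seen. Over all entries that the rule names, the abundant ones and list members included, the sign turned under at least 1 of the 4 scalings for 26 of 211, none of them counted as higher or lower. A counted entry has a fold of at least 4, more than the median shift of any scaling (at most 1.51 in log2), so its sign could hardly turn. Of the 114 counted, 17 lost the call under at least 1 scaling. These were miR-125c-5p, both miR-219-5p entries, miR-2c-3p, miR-31-5p_1 and miR-745-3p in eggs against adults, bantam, let-7-3p, miR-2c-3p and miR-7-5p in metacercariae against adults, bantam-3p and miR-2f-3p in eggs against metacercariae, and bantam, let-7-3p, miR-277, miR-31-5p_1 and novel_mir34 in vesicles. Of 84 recomputed list medians 51 moved and 8 changed sign. Among scalings, lists were recomputed with median-of-ratios size factors and without the most abundant entry. Those scalings move most entries nearly alike, so the rank of a list could change little under them. With a pseudocount of 10 RPM percentiles moved by up to 19.8, and 28 of 28 lists stayed on their side of percentiles 5 and 95. A count of 0 allows 9.93 RPM of miRNA tags in vesicles and 0.350 to 0.841 in the stages. The cause of the shifts was not tested, except that each scaling moves the log2 values of well-counted entries nearly alike by construction. Entries near the pseudocount move otherwise, above all with the authors' RPM. In metacercariae against adults that scaling moved miR-124 from 5.03 to 6.21 and miR-133 from 4.34 to 4.94.

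Counts are given as higher and lower. With median-of-ratios size factors they were 22 and 19 for miRNAs of eggs against adults, 27 and 23 for metacercariae against adults and 13 higher for vesicles. For piRNAs they were 55 and 80 for eggs against adults and 102 higher for metacercariae against adults. With TMM, 23 miRNAs were lower in metacercariae than in adults, 11 were higher in vesicles, and piRNAs of eggs against adults were 61 and 80. Without the most abundant entry 12 were higher in vesicles. With the authors' RPM, 21 miRNAs were lower in eggs than in adults, 30 and 12 differed in metacercariae against adults, and 19 were higher in eggs than in metacercariae. For piRNAs that scaling gave 2 higher in eggs against adults, 2 and 26 in metacercariae against adults, and 7 and 13 in eggs against metacercariae. At a pseudocount of 10 RPM, 21 miRNAs were lower in eggs and 20 in metacercariae than in adults. At a fold of at least 2, miRNAs numbered 19 and 60 in eggs and 69 lower in metacercariae against adults, 10 higher in vesicles, and 60 piRNAs were lower in eggs than in adults. At a fold of at least 8, miRNAs numbered 6 and 14 in eggs and 8 and 21 in metacercariae against adults, and 18 lower in eggs against metacercariae. At that fold piRNAs numbered 10 and 1, 12 and 8, and 13 and 9 in the order eggs and metacercariae against adults and eggs against metacercariae. With at least 100 reads 3 miRNAs were higher in vesicles, and piRNAs numbered 12 and 16, 18 and 24, and 24 and 20 in the same order. Summed by LTR locus, piRNAs numbered 3 and 7, 6 and 4, and 4 and 9. Added after seeing the data, unlisted entries taken as 0 gave 19 higher miRNAs in eggs and 29 in metacercariae against adults, and 46 lower in eggs against metacercariae. For piRNAs that choice gave 668 and 975, 1015 and 1123, and 1007 and 1297, so most piRNA calls at 0 rest on the listing minimum. Also added, known miRNAs alone gave 3 higher in vesicles, and leaving out miR-71a-5p gave 12. Stage-specific miRNAs fell from 43 to 0 at 100 reads or more and, added after seeing the data, to 14 at 40 reads or more.

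The top 5 without the most abundant miRNA held 63.7% in adults, 66.6% in eggs, 72.5% in metacercariae and 67.1% in vesicles, and the top 5 families 76.6%, 74.1%, 79.0% and 88.5%. Among entries seen in both libraries, rho was 0.840 for adults and metacercariae and 0.792 for eggs and metacercariae. With at least 10 reads in either library, r and rho were 0.530 and 0.476 for adults and vesicles, and 0.462 and 0.359 for eggs and vesicles. Added after seeing the data, unlisted entries taken as 0, the values first computed, gave r and rho of 0.893 and 0.889 for adults and eggs, 0.812 and 0.741 for adults and metacercariae, and 0.794 and 0.718 for eggs and metacercariae. Without intergenic tags known miRNAs were 16.8% of vesicle tags, introns 65.4% and precursors 4.12%.

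List medians with median-of-ratios size factors, in the order heterochronic, muscle, nervous system, miR-71/miR-2, vesicle cargo, female schistosome and other flatworm families, were -2.75, 0.93, 1.14, 2.45, 0.73, 0.24 and -0.64 for eggs against adults. They were -1.14, 3.16, 3.27, -0.11, -0.22, 0.037 and 0.25 for metacercariae against adults, and 1.92, 0.79, -1.62, -5.38, -0.47, -0.91 and -0.50 for vesicles. Without the most abundant entry they were -3.62, -0.0034, 0.20, 1.51, -0.21, -0.69 and -1.58 for eggs against adults, -2.14, 2.06, 2.17, -1.21, -1.32, -0.83 and -0.85 for metacercariae against adults, and 1.61, 0.40, -2.07, -5.78, -0.87, -1.31 and -0.89 for vesicles. At a pseudocount of 10 RPM the heterochronic medians were -1.96, -1.02, -0.73 and 0.31 for eggs and metacercariae against adults, eggs against metacercariae, and vesicles. At that pseudocount vesicle cargo was -1.10 and the female list -0.83 in metacercariae against adults, the female list 0.50 in eggs against metacercariae, and nervous system -2.29 and miR-71/miR-2 -6.16 in vesicles. The sign changes were in eggs against adults for muscle, the female list and vesicle cargo (0.011 at a pseudocount of 10 RPM), in metacercariae against adults for the female and other flatworm lists, and in vesicles for muscle.

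The direction of a family turned under at least 1 scaling for miR-1, miR-190, miR-2 and miR-61 in eggs against adults, and for let-7, miR-10, miR-2, miR-2162, miR-219, miR-281 and miR-745 in metacercariae against adults. It turned for bantam, miR-277, miR-61 and miR-71 in eggs against metacercariae, and for miR-10, miR-7, miR-8 and miR-96 in vesicles. Shifts of the median log2 fold not given above the counts were 0.29 with TMM and -0.12 without the most abundant entry in eggs against adults, -0.12 without that entry in metacercariae against adults, and -0.39 with the authors' RPM in vesicles. For piRNAs they were -0.31, -0.23 and -0.13 with median-of-ratios size factors and -0.30, -0.20 and -0.12 with TMM.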

Other observations

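Beyond the fixed lists, several Rfam miRNA classes differed between libraries, and these families were chosen after their values were seen. The mir-71 class held 2113 RPM of annotated tags in eggs, 1183 in metacercariae and 418 in adults. The mir-10 class held 1854 in metacercariae against 4.90 in adults and 2.04 in eggs, and in the same unit the mature miR-10-5p entry held 7632, 7252 and 554. The mir-184 class held 77.7 in metacercariae and 0.721 in adults. In vesicles the let-7 precursor class held 16202 tags, against 1 in adults, 0 in eggs and 130 in metacercariae, and the tRNA class was 38.6-fold above adults. The predicted vesicle miRNAs without a stage match included novel_mir40 of the vesicle table, on scaffold NW_008751668 from 128240 to 128281, with 2013 tags.

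The piRNA test over all loci was set before its result was seen, and its repeats with other entries were added after. The piRNA class was lower in eggs than in adults by annotated tags, and a shift shared by most LTR loci was the hypothesis. Of 103 loci with at least 100 tags over both libraries, 93 (90.3%) were lower in eggs by RPM of annotated tags, with a median log2 ratio of -0.91 and quartiles of -1.48 and -0.42. The median restates the class ratio of 0.524, and egg entries under the listing minimum drop out of these sums. Over the 2591 entries listed in both libraries the class ratio was 0.605, 83 of 94 loci (88.3%) were lower and the median was -0.67, with -0.62 for single entries. With unlisted entries taken as 9 tags the class ratio was 0.601 and 102 of 110 loci were lower, at a median of -0.69. The lower class total in eggs was thus spread over most loci in each of these forms. Neither repeat removes the listing minimum. Entries listed in both need at least 10 tags in each library, and 9 is the most that an unlisted entry can hold. The size without the minimum is therefore not known, and the cause of the lower total was not tested.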
